A study of Drosophila melanogaster with 9 samples.

How the data were processed

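Hemocyte RNA of Drosophila melanogaster larvae was measured by sequencing in 9 libraries, 3 each of a W1118 control, BCR-ABL p210 and BCR-ABL T315I, with 300 third-instar larvae bled per library. Libraries were stranded and made from total RNA after ribosomal RNA depletion, per the labels' protocols. Per the submitters' processing notes, FastQC 0.11.8, HISAT2 2.1.0 and featureCounts 2.0.1 of Subread were used with genome build dm6. The annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. The authors deposited raw counts per gene, with no normalization, in 1 table with 1 column per library. Columns were matched to samples by group and replicate number, and no column was left unused.

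Of 17874 genes listed, 17554 were matched by symbol to the reference annotation (assembly BDGP6.54, release 115, the same assembly as dm6), from which coordinates and overlaps between genes were taken. Among protein-coding genes, 1925 of 1927 whose span was wholly covered by other genes on either strand were at 0 in all libraries, and so were 1056 of 1058 covered only with the other strand included, while 323 of 7267 with a free span were. Counts near a neighbour or an antisense gene are uncertain for that reason, and a 0 for such a gene is not read as absence. Of the genes named, Lsp2, vas, ovo, ftz-f1 and p53 have between 15.4% and 46.2% of their span free. Members of gene families with near-identical copies (Lsp1, Jon, Eig71E, Amy, Hsp70, histone and Bomanin genes) can share reads and are uncertain one by one.

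Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered by filterByExpr (9978 kept), scaled by TMM and fitted by the robust quasi-likelihood model with 1 mean per group over all 9 libraries. Each pair of groups was tested, two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold, and the number with at least a 2-fold change was given beside it. CPM were computed from the deposited counts with library totals multiplied by the TMM factors, and are given as mean ± SD of 3 libraries. Log2 fold changes are edgeR's. Their standard errors were derived as the absolute log2 fold change divided by the square root of the test's F. They are approximate, above all for genes with few counts. Ratios of genes with 1 to 3 counts in a group have a 95% interval for counting error. Depth per library ran from 5.40 to 18.16 M counts, so that 3 counts correspond to between 0.556 and 0.165 CPM; intervals and floors cover counting error only. No 2 libraries held the same values, and replicates differed by more than sampling noise (chi-square per degree of freedom from 14.4 to 99.0). The p-values measure the spread between the biological replicates of the labels. It was estimated over all 3 groups, so p-values of T315I against p210 also carry the spread of the control.

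Gene lists of 44 pathways and cell types, the rule for named genes, the tests of the 3 comparisons and all alternatives except 2 were fixed before the data were examined. The tests of lists of other tissues, of lamellocyte against plasmatocyte markers and of neighbouring genes in the closing section were chosen later. camera was run on the 43 lists with at least 5 tested members with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists, beside camera with an estimated correlation and fry. The genes named were, per comparison, the 8 largest rises and 8 largest falls among genes with adjusted p under 0.05, at least a 2-fold change, no overlap between the groups' libraries, a mean of at least 2 CPM in the higher group and a symbol that is not only an annotation number; up to 4 called members per list by adjusted p, or up to 2 abundant members of a list with none called; and always Abl, Hml, NimC1, PPO1, atilla, Socs36E, puc, CycE, Drs, Lsp2 and ImpE1. A gene named outside the rule is said to be so. The overlap of the comparisons with the control was set beside 20 simulations of unchanged groups that share 3 controls.

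The test was tried on simulated counts with 200 changed genes. All groups were drawn with the same spread per gene, whereas in the data the control varied most, so the outcome may not hold for the data. It recovered 40%, 33% and 34% of 2-fold changes and 74%, 73% and 70% of 4-fold changes for p210 against control, T315I against control and T315I against p210, with 5, 1 and 11 false calls; in the last comparison false calls were above the 5% aimed at.

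Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a stricter filter of 5 CPM in 3 libraries, a block for the replicate number, a fit of the 2 compared groups alone, genes of other tissues left out, a test against a fold change of 1.5, and each library left out in turn. Thinning every library to 5.40 M counts and scaling to the summed counts of the plasmatocyte markers were added after seeing the data, as was a comparison of both transgene groups together with the control. The closing section gives their effect. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The human transgene and mitochondrially encoded genes, all 38 of which were at 0, were not analysed here.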

Results

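Hemocytes, the blood cells of Drosophila melanogaster, were bled from third-instar larvae, and their total RNA was sequenced after ribosomal RNA depletion. The labels give 3 groups of 3 biological replicates, with 300 larvae per library and experiments at 25 °C. They are the W1118 control strain, larvae with the human fusion kinase BCR-ABL p210, which drives chronic myeloid leukaemia, and larvae with BCR-ABL T315I. T315I is the form with a substitution in the kinase domain that blocks imatinib binding. The driver and the cells that expressed the transgenes are not given in the labels, and human BCR-ABL itself was not analysed here.

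Total counts were 5.40, 8.24 and 9.84 M in the control libraries, 18.16, 14.95 and 14.48 M in p210, and 13.86, 14.59 and 15.72 M in T315I. At these depths 3 counts correspond to between 0.165 and 0.556 CPM (counts per M counts of a library), a limit that covers counting error only. Genes of ribosomal RNA held 0.245 to 0.671% of counts in the control libraries and 0.022 to 0.131% in the transgene libraries, and the 10 most abundant genes held 10.26 to 15.74% and 8.89 to 10.66%. The first principal component held 72.4% of the variance and separated the control libraries (scores of -71.7, -121.7 and -73.3) from p210 (49.6 to 66.6) and T315I (24.0 to 39.3). The biological coefficient of variation was 0.402 in the control, 0.199 in p210 and 0.131 in T315I. Of 17874 genes listed, 4416 were at 0 in all 9 libraries and 9978 entered the tests. Genes inside other genes were mostly at 0, with 1925 of 1927 protein-coding genes whose span was covered by others on either strand, against 323 of 7267 whose span was free. PPO1 and atilla, markers of crystal cells and lamellocytes, were such covered genes, so their listing at 0 does not show that they were not expressed. All 38 mitochondrially encoded genes were also at 0, and that list was not tested.

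The first comparison asked what differed between hemocytes of p210 larvae and of control larvae. Strain background was not separated from the transgene. The control libraries also differed from both transgene groups in depth, ribosomal RNA share and spread. Differences from the control, here and for T315I, can therefore not be assigned to BCR-ABL alone. Of JAK/STAT pathway and target genes 13 of 15 rose, of lamellocyte markers 10 of 14, of cytoskeletal partners of the Abl kinase 15 of 20, of DNA replication genes 26 of 29 and of mitosis genes 20 of 34. Of muscle markers 13 of 13 fell, of fat body markers 10 of 13, of cuticle genes 15 of 21 and of midgut genes 14 of 29. As lists, none of these was called by camera once the correlation between genes was estimated (adjusted p = 0.596 with an estimated correlation for each). The JAK/STAT feedback inhibitor Socs36E went from 71.6 ± 62.2 CPM in the control to 324 ± 16.9 in p210 (mean ± SD, n = 3 each), a log2 fold change of 2.17 ± 0.48 (SE). Talin, encoded by rhea, went from 1200 ± 689 to 5140 ± 1040 CPM (edgeR adjusted p = 0.00173), and the fat body storage protein gene Lsp1beta from 17600 ± 6980 to 1530 ± 166 CPM (-3.52 ± 0.32). Hml, a clotting factor gene that marks plasmatocytes, the main phagocytic hemocytes, was at 11600 ± 941 and 12900 ± 3650 CPM and did not pass the test (0.15 ± 0.23, or -0.42 when scaled to plasmatocyte markers).

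In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 5700 of 9978 genes, 2681 higher and 3019 lower in p210. With at least a 2-fold change these were 3503, of which 851 were higher and 2652 lower. The 3 p210 libraries did not overlap the 3 control libraries in 61.6% of tested genes, where chance gives 10%. Scaled to the plasmatocyte markers alone, a choice made after seeing the data, the median log2 fold change over all tested genes was -0.45 in place of 0.05, and 12.5% of called genes were higher in place of 47.0%. This scaling sets the summed counts of 13 markers equal, so abundant ones weigh most, such as Hml (11600 CPM in the control, 12900 in p210) and Ppn (4380 and 14200). Under edgeR's scaling 6 of the 13 were called higher, a count that itself depends on the scaling in question. Which scaling is nearer to the true direction was not tested. Directions below are relative to edgeR's scaling over all genes. List medians given without a value for plasmatocyte scaling are subject to the same shift. Among them are those of Abl interaction and mitosis genes, 0.67 and 0.65 by edgeR's scaling.

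Among 15 measured JAK/STAT pathway and target genes 13 rose and none fell, also 13 adjusted over the list alone. They included the receptor gene dome (1.19 ± 0.16), the phosphatase gene Ptp61F (1.44 ± 0.22), et (1.67 ± 0.25) and the complement-like gene Tep1 (1.59 ± 0.20). Of 14 lamellocyte markers 10 rose and Fhos fell (-1.45 ± 0.24), or 11 rose and 1 fell adjusted over the list alone. Lamellocytes are large flat hemocytes that encapsulate parasites and are rare in healthy larvae. Beside rhea, the integrin gene mys (1.82 ± 0.34) and msn (1.21 ± 0.20), a kinase gene upstream of JNK, rose, with a list median of 2.30. Control replicate 3 stood between its group and the transgene libraries, with Socs36E at 143 CPM against 35.6 and 35.7 and rhea at 1990 CPM against 753 and 845. Without it the lamellocyte median was 3.70 and Socs36E was at 3.15. Of 13 plasmatocyte markers 6 rose and 0 fell, 4 adjusted over the list alone, among them the phagocytosis receptor gene NimC1 (1.61 ± 0.27) and the matrix gene Ppn (1.70 ± 0.32). The plasmatocyte median was 0.41, and -0.15 when scaled to these markers, which draws their own list toward no change by construction. Of 8 crystal cell markers, genes of the cells that melanize wounds, only the transcription factor gene lz rose (0.86 ± 0.19) and only CG7860 fell (-2.07 ± 0.24), the same numbers adjusted over the list alone.

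Fly Abl, the orthologue of the kinase part of the fusion, rose from 174 ± 108 to 777 ± 219 CPM (FBgn0000017, chromosome 3L, 16615866 to 16647882 in dm6), with a log2 fold change of 2.15 ± 0.39 and edgeR adjusted p = 0.00201. Without control replicate 3, at 299 CPM against 114 and 110, it was 2.76. Whether reads of the human transgene add to the counts of fly Abl was not tested. Of 20 Abl interaction and cytoskeleton genes 15 rose and 0 fell, 16 adjusted over the list alone, with the adaptor gene Abi at 1.01 ± 0.16 and the GTPase genes Rho1 and Cdc42 at 0.93 ± 0.14 and 1.07 ± 0.18. DNA replication genes rose in 26 of 29 cases, 27 adjusted over the list alone, with the polymerase gene PolA1 at 1.28 ± 0.18, the helicase gene Mcm3 at 1.30 ± 0.21 and the cyclin gene CycE at 0.78 ± 0.18. Mitosis genes rose in 20 of 34, the same number adjusted over the list alone, with the kinase gene aurB at 1.48 ± 0.21 and the condensin gene glu at 1.23 ± 0.19. In the PI3K/TOR and insulin list 10 of 17 rose and 1 fell, 10 and 1 adjusted over the list alone, with the PI3 kinase gene Pi3K92E at 0.82 ± 0.14 and S6k at 1.34 ± 0.29. JNK pathway genes numbered 8 higher and 2 lower of 14, the same adjusted over the list alone, with the kinase gene bsk at 0.76 ± 0.15 and the protease gene Mmp1 at 1.48 ± 0.30. The JNK target puc was not called, at 0.47 ± 0.21, or -0.06 when scaled to plasmatocyte markers, but passed without control replicate 1 (0.70). Chromatin genes of the SWI/SNF and Polycomb groups rose in 9 of 17, also 9 adjusted over the list alone, with Psc at 1.11 ± 0.22. Medians of the PI3K/TOR and chromatin lists, 0.51 and 0.43, were -0.04 and -0.10 when scaled to plasmatocyte markers. In the same libraries the fat body, muscle, cuticle and midgut lists had medians between -3.21 and -2.66, with that of midgut genes at -3.87 without p210 replicate 2, and ribosomal RNA genes held 0.022 to 0.131% of counts against 0.245 to 0.671% in the control.

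All 13 muscle markers fell, 13 adjusted over the list alone, such as the myosin light chain gene Mlc1 (-3.45 ± 0.32) and the titin-like gene sls (-2.56 ± 0.23). Of 13 fat body markers 10 fell and 1 rose, the same adjusted over the list alone, with Lsp1alpha at -4.97 ± 0.53, Lsp2 at -4.19 ± 0.49 and the lipoprotein gene apolpp at -2.83 ± 0.30. Cuticle genes fell in 15 of 21, 15 adjusted over the list alone, with Lcp2 at -5.09 ± 0.51. Midgut digestive genes fell in 14 of 29, 12 adjusted over the list alone, with the maltase gene Mal-A5 at -3.65 ± 0.36. Heat shock genes fell in 13 of 17, also 13 adjusted over the list alone, with the small chaperone genes Hsp26 at -2.87 ± 0.37 and Hsp23 at -2.58 ± 0.36. Cytochrome P450 genes, which act on steroids and foreign compounds, fell in 30 of 51 and rose in 4, the same adjusted over the list alone, with Cyp4d1 at -4.19 ± 0.51. Of 13 roX and Y-linked genes 11 fell, 11 adjusted over the list alone, with the male fertility gene kl-3 at -2.65 ± 0.38, or -1.99 without control replicate 2. The roX RNAs of dosage compensation were not called, with lncRNA:roX1 at 894 and 1040 CPM. The largest rises included the immunoglobulin-domain gene dpr4 (5.79 ± 0.66), the calcium channel subunit gene Ca-beta (5.05 ± 0.53) and the receptor kinase gene Tie (3.53 ± 0.37). Among the largest falls, Eig71Ed had 126 counts in the control and 1 in p210, a ratio of 255 with a 95% counting interval of 45.0 to 10200, and the clotting gene fon fell by 5.89 ± 0.85, or by 4.60 without control replicate 1.

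camera with a preset correlation of 0.01 called 16 of 43 lists: JAK/STAT, lamellocyte, plasmatocyte, Abl interaction, S phase, mitosis, PI3K/TOR, JNK and SWI/SNF genes upward, and fat body, muscle, cuticle, midgut, roX and Y-linked, heat shock and cytochrome P450 genes downward. None held with an estimated correlation, where the adjusted p = 0.596 with an estimated correlation for 15 of them and adjusted p = 0.658 with an estimated correlation for PI3K/TOR genes. Even with the preset correlation, calls of camera were lost for plasmatocyte markers without control replicate 1 (adjusted p = 0.0592) or p210 replicate 3 (0.0677), for PI3K/TOR genes without control replicate 3 (0.0631) or p210 replicate 3 (0.0506), for chromatin genes without control replicate 3 (0.0722), for heat shock genes without control replicate 1 (0.0957) and for JNK genes without any of 7 libraries (0.0540 to 0.0848). Calls were gained for Bomanin genes in 6 of the 9 fits with 1 library left out (0.0207 to 0.0417), for Toll and IMD genes in 3 (0.0372 to 0.0483), for phagocytic receptors without control replicate 3 (0.00771), for glycolysis genes without control replicate 2 (0.0422), and for DNA damage and ecdysone genes without p210 replicate 3 (0.0403 and 0.0314). fry called 25 lists, and other splits of the same 6 libraries gave up to 20 camera calls. Member counts were not tested against other genes, of which 57.1% were called in either direction, 2681 of 9978 higher and 3019 lower. Of the 16 lists, plasmatocyte markers (6 of 13), midgut genes (14 of 29) and chromatin genes (9 of 17) had a share below those 57.1%, and mitosis genes (20 of 34) a share near it. Calls in these lists were all higher, or all lower for midgut genes. Each share was above that of all genes called in the same direction.

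**Figure D1:**
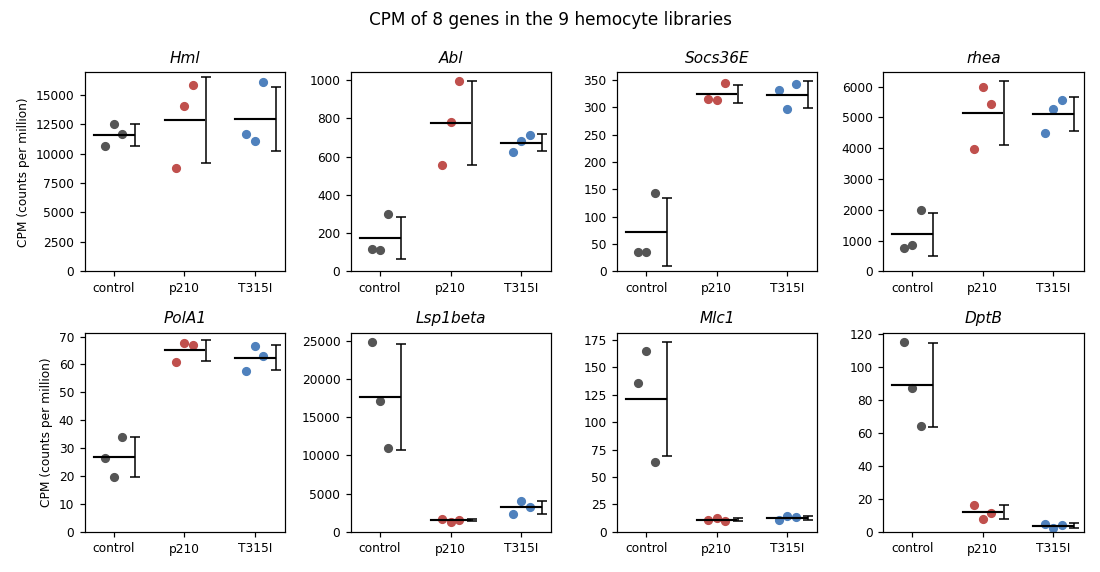
CPM of 8 genes in each of the 9 libraries (points, in replicate order within a group), with the mean of each group (black line) and its SD over 3 libraries (bar at the right of each group). Control replicate 3, the point on the right of each control group, has 143 CPM of Socs36E against 35.6 and 35.7, and Hml is at 11600 to 12900 CPM on average in all groups.

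The second comparison asked the same of T315I larvae against the control. Of JAK/STAT pathway and target genes 12 of 15 rose, of lamellocyte markers 9 of 14, of Abl-related cytoskeletal genes 13 of 20, of DNA replication genes 23 of 29 and of mitosis genes 17 of 34. Of muscle markers 13 of 13 fell, of fat body markers 10 of 13, of cuticle genes 13 of 21 and of midgut genes 23 of 29. As lists, camera called none of these with the correlation estimated (adjusted p = 0.604 with an estimated correlation for lamellocyte, Abl, replication and mitosis genes, and adjusted p = 0.531 with an estimated correlation for the others). Socs36E stood at 323 ± 24.1 CPM against 71.6 ± 62.2 in the control (2.17 ± 0.48, or 3.18 without control replicate 3), and rhea at 5110 ± 543 CPM against 1200 ± 689 (edgeR adjusted p = 0.00388). Abl rose to 673 ± 45.7 CPM (1.95 ± 0.38, edgeR adjusted p = 0.00542), and to a log2 fold change of 2.59 without control replicate 3. Lsp1beta fell to 3200 ± 850 CPM (-2.46 ± 0.31), while Hml was at 12900 ± 2730 CPM and was not called (0.16 ± 0.23, or -0.34 when scaled to plasmatocyte markers).

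edgeR called 4915 of 9978 genes with Benjamini-Hochberg adjustment, 2048 higher and 2867 lower in T315I. At least a 2-fold change was seen in 3125 of them, 640 higher and 2485 lower. The T315I libraries did not overlap the control libraries in 58.2% of tested genes, against 10% by chance. Scaled to the plasmatocyte markers, the median over all genes was -0.49 and 10.5% of called genes were higher, in place of -0.02 and 41.7%. Medians of Abl interaction and mitosis genes, 0.53 and 0.44 by edgeR's scaling, are subject to the same shift.

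Of 15 JAK/STAT pathway and target genes 12 rose and 0 fell, 14 adjusted over the list alone, with the humoral stress gene TotA at 1.74 ± 0.27, Tep1 at 1.47 ± 0.20 and dome at 1.10 ± 0.16. Lamellocyte markers rose in 9 of 14 and 1 fell, 11 and 1 adjusted over the list alone, with mys at 1.72 ± 0.34, betaTub60D at 1.08 ± 0.23 and a median of 2.24, or 3.65 without control replicate 3. Plasmatocyte markers rose in 4 of 13, also 4 adjusted over the list alone, with NimC1 at 1.37 ± 0.27 and a median of 0.27. That median was -0.20 when scaled to these markers, a shift set by construction. Crystal cell markers again had 1 higher (lz, 0.86 ± 0.19) and 1 lower (CG7860, -2.08 ± 0.24) of 8, 1 and 1 adjusted over the list alone. Replication genes rose in 23 of 29, 25 adjusted over the list alone, with PolA1 at 1.22 ± 0.18, PolE1 at 1.16 ± 0.21 and CycE at 0.69 ± 0.18. Mitosis genes rose in 17 of 34, 17 adjusted over the list alone, with glu at 1.24 ± 0.19 and the checkpoint gene BubR1 at 1.11 ± 0.20. Abl interaction and cytoskeleton genes rose in 13 of 20, 14 adjusted over the list alone, with Abi at 0.97 ± 0.16 and trio, an exchange factor gene for Rac, at 1.02 ± 0.18. JNK pathway genes numbered 6 higher and 1 lower of 14, SWI/SNF and Polycomb genes 8 higher of 17, and PI3K/TOR genes 7 higher and 1 lower of 17, each the same adjusted over the list alone; puc was at 0.22 ± 0.21, or -0.23 when scaled to plasmatocyte markers. The medians of these lists, 0.44, 0.40 and 0.40, were -0.02, -0.06 and -0.06 when scaled to plasmatocyte markers. In these libraries the muscle, fat body, cuticle and midgut lists had medians of -2.75, -2.46, -2.14 and -3.65, the last -2.55 without control replicate 3.

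All 13 muscle markers fell, 13 adjusted over the list alone, with Mlc2 at -3.18 ± 0.33. Fat body markers fell in 10 of 13 and 1 rose, the same adjusted over the list alone, with Fbp2 at -3.53 ± 0.39 and Lsp2 at -2.63 ± 0.46. Midgut digestive genes fell in 23 of 29, also 23 adjusted over the list alone, with the amylase gene Amy-d at -6.69 ± 1.10, or -5.41 without control replicate 1, and the trypsin gene epsilonTry at -4.96 ± 0.87. Cuticle genes fell in 13 of 21, 14 adjusted over the list alone, with Lcp1 at -4.52 ± 0.52. Heat shock genes fell in 12 of 17, 12 adjusted over the list alone, with Hsp23 at -2.44 ± 0.36. Cytochrome P450 genes fell in 26 of 51 and rose in 3, 27 and 3 adjusted over the list alone, with Cyp6w1 at -4.42 ± 0.61. The roX and Y-linked list had 11 lower of 13, 11 adjusted over the list alone, with PRY at -1.97 ± 0.42. The antimicrobial peptide gene DptB fell from 89.1 ± 25.4 to 3.69 ± 1.46 CPM (-4.58 ± 0.39). The largest rises included dpr2 (4.88 ± 1.02), which was at 182 CPM in T315I replicate 3 against 18.1 in replicate 1 and at 3.08 without replicate 3, and zye (3.31 ± 0.61, or 4.24 without control replicate 3). For dpr2, which was not called in p210 (0.95 ± 0.99), the difference between T315I and p210 was not called by edgeR (adjusted p = 0.632), which does not show that they are alike. The digestive protease gene Jon44E, among the largest falls, had 250 counts in the control and 1 in T315I, a ratio of 470 with a 95% counting interval of 83.6 to 18600. Control replicate 3 held 21.3 CPM of Jon44E against 1.66 and 1.77, and the log2 fold change of -8.00 ± 1.66 was -5.73 without it.

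camera with the preset correlation called 15 lists, the 16 named for p210 without PI3K/TOR genes. All were lost when the correlation was estimated, with adjusted p = 0.531 with an estimated correlation for JAK/STAT, muscle, fat body, cuticle and midgut genes, adjusted p = 0.676 with an estimated correlation for heat shock genes and adjusted p = 0.604 with an estimated correlation for the remaining 9. With the preset correlation, camera lost heat shock and cytochrome P450 genes without control replicate 1 (adjusted p = 0.154 and 0.0886), chromatin genes without control replicate 3 (0.0667), plasmatocyte markers without control replicate 1, control replicate 2 or T315I replicate 3 (0.0520 to 0.0575), and JNK genes without any of 8 libraries (0.0520 to 0.0743). Calls were gained for PI3K/TOR genes without p210 replicate 1 (0.0328), for glycolysis, ecdysone and melanization genes without control replicate 2 (0.0251, 0.0411 and 0.0429), and for ecdysone genes and phagocytic receptors without control replicate 3 (0.0338 and 0.00203). fry called 22 lists, and other splits of these 6 libraries gave up to 20 camera calls. Member counts were not tested against other genes, of which 49.3% were called in either direction, 2048 of 9978 higher and 2867 lower. Of the 15 lists, plasmatocyte markers (4 of 13) and chromatin genes (8 of 17) had a share below those 49.3%, and mitosis (17 of 34) and JNK genes (7 of 14) a share near it. Except for 1 JNK gene these calls were all higher. The share called higher was above that of all genes in each of these lists.

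**Figure D2:**
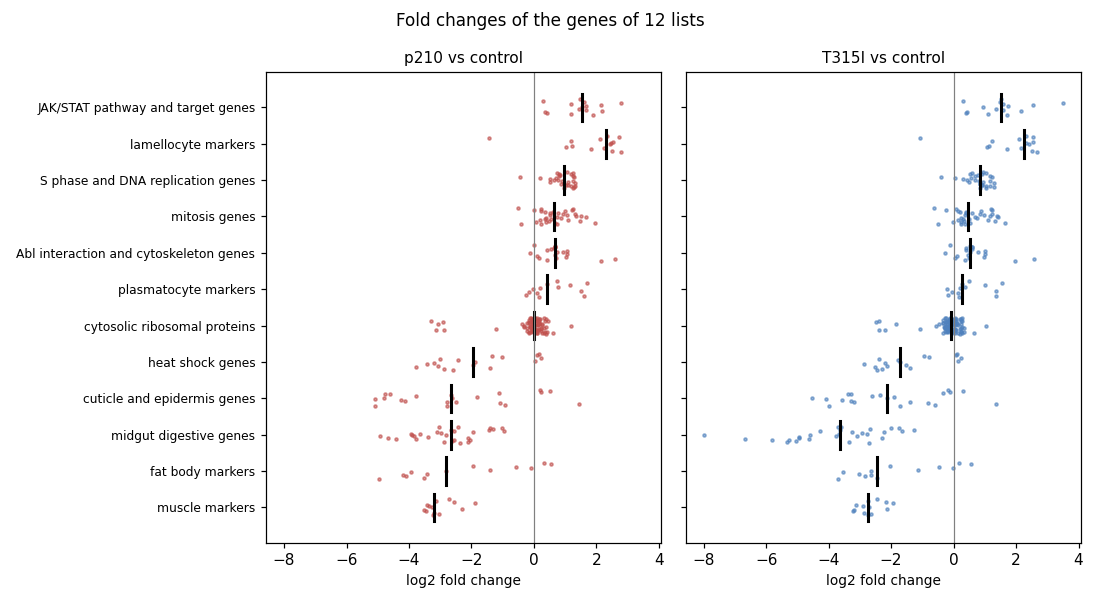
Log2 fold changes against the control of each measured member of 12 gene lists (points) and the list's median (black line), for p210 on the left and T315I on the right, relative to edgeR's scaling over all genes. Lamellocyte markers have medians of 2.30 and 2.24, and muscle markers of -3.21 and -2.75. The plasmatocyte medians of 0.41 and 0.27 turn to -0.15 and -0.20 when libraries are scaled to those markers, a shift that the scaling sets by construction.

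Both comparisons changed largely the same genes: 1987 were higher and 2707 lower in both, 4694 in all, and none were called in opposite directions. The genes rhea, Socs36E, Abl and PolA1 are among those higher in both and Lsp1beta, Mlc1 and Hsp23 among those lower in both. Because both comparisons share the 3 control libraries, the same overlap was simulated 20 times with unchanged groups. This gave a mean of 0.9 genes higher and 0.1 lower in both, while independent lists of these sizes would share 550 and 867. The simulation drew genes independently with no group difference, so hardly any were called by construction. Controls that differed from all other libraries for any reason could also give a large overlap. The simulation cannot tell this from a shared effect of the transgenes. Over all tested genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.95 against 0.762 in the simulations, and a covariance of 1.91 against 0.149. A further 1006 genes were called in p210 alone and 221 in T315I alone, and membership of either set does not show a difference between the groups, which is tested by the third comparison.

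Toll and IMD, antimicrobial peptide, phagocytic receptor, melanization and Ras/MAPK genes moved both ways in both comparisons, while over all genes Bomanin genes were called only upward, and in p210 alone, and glycolysis genes only downward. Toll and IMD pathway components had 11 higher and 4 lower of 18 in p210 and 9 higher and 4 lower in T315I, the same numbers adjusted over the list alone. The receptor gene Tl rose (1.61 ± 0.20 and 1.47 ± 0.20), as did the NF-kappaB gene Dif (2.26 ± 0.35 and 1.92 ± 0.35, or 2.85 and 2.55 without control replicate 3), while the protease gene grass fell (-3.31 ± 0.51 and -2.73 ± 0.49, or -2.52 and -1.92 without control replicate 1). Antimicrobial peptide genes had 3 higher and 3 lower of 12 in p210, with CecC at 2.50 ± 0.32 and DptB at -2.90 ± 0.36, and 1 higher and 5 lower in T315I, the same adjusted over the list alone. Of 5 Bomanin and daisho genes, effectors of Toll signalling, 4 rose in p210, also 4 adjusted over the list alone, such as BomS1 (3.71 ± 0.85). In T315I 0 were called by edgeR, and 0 adjusted over the list alone, with BomS1 at 1.79 ± 0.91; the difference between T315I and p210 in BomS1 was not called over all genes (edgeR adjusted p = 0.999), which does not show that they are alike. Drs, another Toll target, was not called in either (1.09 ± 0.46 and 0.46 ± 0.46, the latter -0.02 when scaled to plasmatocyte markers), although it passed in p210 without control replicate 2 (1.61). Phagocytic and scavenger receptors had 10 higher and 6 lower of 20 in p210 and 8 higher and 5 lower in T315I, the same adjusted over the list alone, with the engulfment receptor gene drpr at 1.09 ± 0.17 and 1.14 ± 0.17 and NimC2 at -2.51 ± 0.29 and -1.61 ± 0.28. Melanization and clotting genes had 2 higher and 8 lower of 15 in both, or 2 and 9 in p210 and 2 and 8 in T315I adjusted over the list alone, with the tyrosine hydroxylase gene ple at -4.29 ± 0.51 and -4.44 ± 0.51. Ras/MAPK genes had 9 higher and 3 lower of 19 in p210 (10 and 4 adjusted over the list alone) and 6 higher and 2 lower in T315I (6 and 2 adjusted over the list alone), with the transcription factor gene pnt at 1.88 ± 0.34 and 1.53 ± 0.33. Glycolysis genes fell in 7 of 13 in p210 and in 5 in T315I (7, and 6 with 1 higher, adjusted over the list alone), with Pgi at -1.24 ± 0.12 and -1.06 ± 0.12. In both comparisons the fat body and muscle markers were lower, with medians between -3.21 and -2.46.

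The third comparison asked whether T315I hemocytes differed from p210 hemocytes. By the planned test dpr4, which encodes a neuronal immunoglobulin-domain protein, was the single gene called, at 16.4 ± 9.89 CPM in p210 and 0.0687 ± 0.00303 in T315I (3R, 11533483 to 11542949 in dm6). Its log2 fold change was -7.71 ± 0.74 (edgeR adjusted p = 0.0159), and its 711 and 3 counts give a p210 to T315I ratio of 220 with a 95% counting interval of 75.0 to 1070. Control libraries held 0.302 ± 0.183 CPM of it. Socs36E (0.00 ± 0.46), rhea (-0.01 ± 0.34), Abl (-0.21 ± 0.37) and Hml (0.01 ± 0.23) were close to equal in the 2 groups, although their standard errors leave room for differences. These errors come from the fit over all 9 libraries and so include the spread of the control. Socs36E was at 324 ± 16.9 CPM in p210 and 323 ± 24.1 in T315I, but at 71.6 ± 62.2 in the control.

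At an unadjusted p under 0.05, edgeR gave 348 genes, where 499 would pass by chance, and libraries did not overlap in 16.7% of tested genes, against 10% by chance. The p-values use a spread estimated with the control libraries, whose biological coefficient of variation was 0.402 against 0.199 in p210 and 0.131 in T315I. Simulated data with known changes had 34% of 2-fold and 70% of 4-fold changes recovered in this comparison, so smaller differences can be missed. The simulation gave all groups the same spread, which the real groups did not have, so these shares may not hold for the data. DESeq2 called 36 genes, 9 higher and 27 lower in T315I, among them the antimicrobial peptide genes DptA and DptB (edgeR adjusted p = 0.424 and 0.433). Fitted to the 6 libraries of these groups alone, edgeR called 6 genes, with DptA among them (-2.74, adjusted p = 0.0443). limma-voom called 1, CG10407, a gene outside the naming rule, and not dpr4. The dpr4 call was lost without p210 replicate 3 and without each T315I replicate, with edgeR adjusted p between 0.0885 and 0.248.

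No member of any of the 43 lists was called over all genes. Adjusted over the list alone, 4 antimicrobial peptide genes and 3 Bomanin genes were lower in T315I, 2 fat body markers were higher and 1 cytochrome P450 gene was lower. The antimicrobial peptide list had a median of -0.90, and DptB stood at 11.8 ± 4.16 CPM in p210 and 3.69 ± 1.46 in T315I. Bomanins had a median of -1.71, with BomS1 at -1.92 ± 0.68. The storage protein genes Lsp1beta and Lsp1gamma, at 1.06 ± 0.30 and 1.26 ± 0.41, and a fat body median of 0.27 lay on the T315I side.

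camera with the preset correlation called 12 lists. Higher in T315I were fat body, muscle, cuticle, roX and Y-linked, heat shock and cytochrome P450 genes, and lower were antimicrobial peptide, Bomanin, midgut, PI3K/TOR, S phase and mitosis genes. The midgut median of -0.88 was 0.01 without p210 replicate 2. fry called 0 lists. With the correlation estimated none was called, with adjusted p = 0.888 with an estimated correlation for the fat body, antimicrobial peptide and Bomanin lists and adjusted p = 0.986 with an estimated correlation for the other 9. Other splits of these 6 libraries gave up to 20 list calls, and 4 lists were called without T315I replicate 3.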

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

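The comparisons of lists of other tissues, of lamellocyte with plasmatocyte markers and of neighbouring genes were chosen only after the result was seen. So were the permutation of libraries, thinning, the reading of dpr4 without control libraries, and the comparison of both transgene groups together with the control.

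The third comparison gave the results that differ between the 2 transgene groups. The neuronal immunoglobulin-domain gene dpr4 had a log2 fold change of -7.71 in T315I against p210. Median log2 fold changes of lists called with the preset correlation were 0.27 for fat body markers, 0.35 for muscle markers, 0.49 for cuticle genes, 0.64 for roX and Y-linked genes, 0.39 for heat shock genes and 0.33 for cytochrome P450 genes. They were -0.88 for midgut genes, -0.90 for antimicrobial peptide genes, -1.71 for Bomanin and daisho genes, -0.14 for PI3K/TOR genes, -0.12 for S phase genes and -0.12 for mitosis genes. The midgut median was 0.01 without p210 replicate 2. None of these lists was called with an estimated correlation.

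Lower counts of fat body, muscle, cuticle and midgut genes in both transgene groups could come from a smaller share of RNA from those tissues in the bleeds, from lower expression in hemocytes, or from shallower control libraries. If the share alone differed and hemocytes did not express the listed genes, lists of other tissues would fall alike. Over 8 lists they moved apart with genes permuted in p210 (permutation p = 0.00028) and with whole libraries permuted over both groups (exact permutation p = 0.0357). In p210, however, 3 of 8 germline, 2 of 9 neuronal and 2 of 8 imaginal disc genes rose, while 4, 2 and 5 fell. Whether hemocytes express these genes was not tested, so the 8 lists cannot decide on a common share. For the 4 lists of fat body, muscle, cuticle and midgut genes a common share stays open: permuting genes, which takes genes of a list as independent, gave permutation p = 0.61 in p210 and 5.0e-05 in T315I, permuting libraries gave exact permutation p = 0.31, and without control replicate 3 the midgut median in T315I was -2.55 in place of -3.65. With all libraries thinned to 5.40 M counts the medians in p210 and T315I were -2.89 and -2.51 for fat body and -3.26 and -2.81 for muscle genes. They were -4.47 and -3.36 for cuticle and -2.53 and -3.89 for midgut genes. Genes were filtered anew after thinning, and the cuticle medians without it were -2.66 and -2.14. Thinning keeps each gene's expected share of counts, so it could hardly have removed differences of this size. It therefore does not decide on the lower total counts of the controls. Different shares for each tissue, expression within hemocytes and the higher ribosomal RNA share of the control libraries were not tested.

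Higher lamellocyte markers in both transgene groups could come from more lamellocytes, from higher expression per cell, or from a smaller share of other tissues that raises every hemocyte gene. In that last case plasmatocyte and lamellocyte markers would rise alike, provided that other tissues express neither list, which was not tested. Their mean log2 fold changes in p210 were 0.61 and 1.85. Permuting genes, which takes genes of a list as independent, gave permutation p = 0.00215, and permuting libraries of both groups gave exact permutation p = 0.0119. Lamellocyte markers thus rose further than plasmatocyte markers. As the proviso was not tested, these values do not decide whether a smaller share of other tissues was the only cause. With libraries thinned to 5.40 M counts the lamellocyte median was 2.28 in p210 and 2.19 in T315I. Thinning keeps expected shares of counts, so it could hardly have changed these medians much. Control replicate 3 lies between the other controls and the transgene libraries in these genes, and the strain background of the W1118 control was not separated from the transgene. Cell numbers were not analysed here.

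Genes that differ between the transgene groups, such as dpr4, could follow the chromosomal site of each insertion or the substitution. Of 20 genes with coordinates and an unadjusted p under 0.001, 7 pairs lay within 200 kb of one another against 0.703 for random genes (permutation p = 1.0e-04, the smallest that 10000 permutations give). Of the 20 genes with the smallest p, with CG10407, which has no coordinates, in place of gukh, 6 pairs were as close, and 9 other splits of the libraries gave up to 5, a comparison and a stricter reading added after the first outcome, so the test cannot tell. The gene dpr4 was in none of the 7 pairs, so the test does not bear on it. Those pairs lay at separate places on 3L and 3R and not in a single region. Without the control libraries dpr4 was still called (edgeR adjusted p = 0.0331), so its call does not rest on their spread; the outcome written before that fit, at least 1.5 times as many calls, was met with 6 genes against 1, but it bears on how few genes were called and not on why they differ. Insertion sites are not given in the sources used here.

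Other splits of the same libraries were tried for each count. For genes called, 1 of 10 splits was as large for p210 against control, 1 of 10 for T315I against control and 1 of 10 for T315I against p210, the real split each time, with 5700, 4915 and 1 genes against 0 in the highest other split. For gene lists called, 6, 7 and 6 of 10 splits were as large, with up to 20 lists in another split. Each other split of 6 libraries exchanged 1 library between the groups, so it kept part of their difference and widened the spread within groups. The smallest share that 10 splits can give is 1 of 10. These counts of genes and lists therefore cannot tell a group difference from an accident of grouping. With both transgene groups together against the control, 6053 genes were called, and 1 of 84 splits was as large, the highest other split giving 1232.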

How the results depend on the processing

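No test in this part was chosen for a result, but thinning and scaling to plasmatocyte markers were chosen only after the result was seen. No gene called in the main analysis was called in the opposite direction under any setting. The cause of the changes below was not tested, except where fewer genes, lists or libraries were tested by construction.

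Against the control, genes called in p210 numbered 4796 to 6222 with 1 library left out, and in T315I 3346 to 5410. The stricter filter, which tests fewer genes, gave 3671 for p210, and 1990 and 1845 with at least a 2-fold change in p210 and T315I. The test against a fold change of 1.5 gave 3351 and 2571. Upper-quartile scaling had 36.0% and 34.5% of calls higher in p210 and T315I, and plasmatocyte scaling 12.5% and 10.5%, against 47.0% and 41.7%. The genes grp and Atf6, called in T315I at 0.41 each (edgeR adjusted p = 0.00831 and 0.02905), were at -0.05 each with plasmatocyte scaling. Under that scaling 37 genes named in p210 and 39 others in T315I kept their direction but lost their call. A block for the replicate number gave 5299, 4125 and 1 genes, and libraries of the same number were not more alike than others. Lists called in p210 and T315I against the control, 16 and 15 in the main analysis, were 18 and 15 with that block. They were 11 and 12 with the stricter filter and 19 and 19 without a filter.

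Between the transgene groups, genes called were 36 with DESeq2 (34 with at least a 2-fold change), 2 without a filter (2), 6 with the 2 groups alone (6), 5 with plasmatocyte scaling (5) and 0 with thinned counts (0). They were 0 without p210 replicate 3 and 4 without p210 replicate 1, with the same numbers at 2-fold. Lists called were 6 with the stricter filter, 6 with thinned counts, 4 without T315I replicate 3 and 13 without p210 replicate 1. Salivary gland genes had a median of -0.27, which was -0.87 without T315I replicate 3 and 2.31 without p210 replicate 2; midgut genes went from -0.88 to -0.90 without T315I replicate 1 and 0.01 without p210 replicate 2.

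With genes of other tissues left out 10, 9 and 7 lists were called in p210 against control, T315I against control and T315I against p210. By construction 4 called lists were not tested in each; plasmatocyte and JNK lists against the control and heat shock genes in the last comparison were tested and no longer called. camera with an estimated correlation called 0, 0 and 0. Depth limits the control most, where 3 counts are up to 0.556 CPM.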

Other observations

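No explanation is tested in this part, so no test was chosen only after the result was seen. Lists of metabolism, protein synthesis and stress genes mostly had calls in both directions. In several most members were not called, such as 79 of 88 ribosomal and 57 of 79 oxidative phosphorylation genes in p210. Of all tested genes 57.1% were called in p210 and 49.3% in T315I. Of 88 cytosolic ribosomal protein genes 3 rose and 6 fell in p210, and 2 and 6 in T315I (1 and 6, and 2 and 6, adjusted over the list alone). Those that fell included the testis-type paralogs RpL22-like (-3.29 ± 0.51 in p210) and RpL10Aa (-2.87 ± 0.50). Of 79 nuclear-encoded oxidative phosphorylation genes 9 rose and 13 fell in p210, and 4 and 13 in T315I (3 and 12, and 2 and 10, adjusted over the list alone), among them the testis cytochrome c gene Cyt-c-d (-2.84 ± 0.47 in p210). Lipid synthesis and storage genes had 5 higher and 8 lower of 17 in p210 and 5 and 7 in T315I (5 and 9, and 5 and 8, adjusted over the list alone), with the lipocalin gene NLaz at -3.74 ± 0.37 in p210. The ribosomal and oxidative phosphorylation medians in p210, 0.01 and 0.13, were -0.46 and -0.33 when scaled to plasmatocyte markers. Redox genes had 5 higher and 5 lower of 18 in p210 and 3 and 4 in T315I (5 and 5, and 2 and 4, adjusted over the list alone), with Trx-2 at 1.43 ± 0.18 and the catalase gene Cat at -1.34 ± 0.16 in p210. Of 29 glutathione S-transferase genes 6 rose and 8 fell in p210, and 5 and 8 in T315I, the same adjusted over the list alone. Unfolded protein response genes had 1 higher and 3 lower of 16 in p210 and 1 and 1 in T315I (1 and 1, and 0 and 1, adjusted over the list alone). Of 19 replication-dependent histone genes 1 rose in p210, and 1 rose and 2 fell in T315I, with 0 in each adjusted over the list alone.

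Lists of development and cell death genes mostly had calls in both directions. In p210, however, 12 of 19 matrix, 12 of 19 DNA damage and 12 of 18 autophagy genes were not called. Hippo pathway genes had 8 higher and 3 lower of 14 in p210 and 7 and 3 in T315I, the same adjusted over the list alone, with the co-activator gene yki at 1.25 ± 0.20 and the cadherin gene ds at -2.58 ± 0.38 in p210. Notch pathway genes had 1 higher and 2 lower of 9 in p210 and 1 and 1 in T315I (1 and 1 in each adjusted over the list alone). Lymph gland and progenitor markers had 5 higher and 3 lower of 9 in p210 and 5 and 2 in T315I, the same adjusted over the list alone. Matrix genes had 3 higher and 4 lower of 19 in p210 and 4 and 4 in T315I, the same adjusted over the list alone, with the perlecan gene trol at -2.72 ± 0.23 in p210. Ecdysone response genes had 1 higher and 7 lower of 15 in p210 and 1 and 8 in T315I, the same adjusted over the list alone, with the nuclear receptor gene Eip78C at -2.34 ± 0.31 in p210. ImpE1, an ecdysone-induced gene, was at 20.7 CPM in control replicate 1 against 1.77 and 0.948, and its -3.84 ± 1.28 in p210 was -1.30 and not called without that library, as was its -4.33 ± 1.33 in T315I, at -1.79. DNA damage genes had 6 higher and 1 lower of 19 in p210 and 7 and 1 in T315I (6 and 1 in each adjusted over the list alone). Apoptosis genes had 5 higher and 4 lower of 12 in p210 and 5 and 3 in T315I (5 and 4, and 5 and 5, adjusted over the list alone), and autophagy genes 5 and 1 of 18 and 4 and 1, the same adjusted over the list alone. Imaginal disc genes had 2 higher and 5 lower of 8 in both, the same adjusted over the list alone, and germline genes 3 and 4 of 8 and 2 and 4 (3 and 4 in each adjusted over the list alone). Neuronal genes had 2 and 2 of 9 in p210 and 1 and 2 in T315I, the same adjusted over the list alone. Salivary gland genes had 1 higher and 3 lower of 9 in p210 and 0 and 2 in T315I, the same adjusted over the list alone, with medians of -3.15 and -4.22 that were 0.08 and -0.90 without control replicate 3. None of these lists was called by camera with the preset correlation. Medians were positive and means negative in both comparisons for the crystal cell (0.15 and -0.08 in p210), Notch (0.22 and -0.43), Hippo (0.43 and -0.07), oxidative phosphorylation (0.13 and -0.28) and matrix lists (0.14 and -0.17), in p210 for apoptosis (0.01 and -0.46), ribosomal (0.01 and -0.13) and redox genes (0.06 and -0.28), and in T315I for lymph gland markers (0.73 and -0.05), glutathione S-transferases (0.05 and -0.01) and neuronal genes (0.01 and -0.09).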
